A study of Rattus norvegicus with 9 samples.

How the data were processed

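Ribosome footprints were sequenced from rat IEC6 cells given 4 µM of compound 7f, 4 µM of compound 7l or vehicle (0.5% DMSO) for 60 min, with cycloheximide in the harvest and lysis buffers per the labels. Each group holds 3 libraries, and the comparisons were 7f with vehicle, 7l with vehicle and 7l with 7f. The authors gave a map of raw footprint counts per codon for each library. Per the submitters' processing notes, reads were aligned with Bowtie 1.1.2 and transcript levels estimated with kallisto 0.42.5. The deposited code reduces Ensembl rat cDNAs of the Rnor6 assembly to transcripts that were the only expressed isoform of their gene (kallisto TPM of 1 or more in vehicle), filters alignments on their number of sites, places each read by a P site 14 nt from its 5' end and sums counts per codon. The processing notes name the human build GRCh38, which differs from the build of the code and from the rat transcript identifiers in the files, so no genome coordinates are given here. The authors' result tables, per the file headers, hold mean signals per group (counts scaled by DESeq size factors in the deposited code), the ratio of the means as a fold change, its log2 value, the p-value and adjusted p-value of DESeq, and the codon position of the authors' largest cumulative difference. The deposited count table holds raw counts per coding sequence.

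The labels of the deposited count table and of the codon maps conflict. Columns of the count table that their description gives to 7f hold the summed codon maps of the vehicle libraries in 100% of transcripts, and those given to vehicle hold the maps of 7f, while the 7l columns match. Where they could be matched, the authors' own means follow the codon maps' labels, which were therefore used throughout, and the count table by its column descriptions was kept as an alternative.

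The 10762 coding sequences hold 6003819 codons, and 8 had no footprint in any library. The 9 libraries held between 3878718 and 19039078 footprints each, and between 10070 and 10676 coding sequences had 10 or more. Gene symbols were those of the files. Of these, 9414 stood in a rat gene table, 473 matched only a synonym, and 12 transcripts had no symbol. Symbols shared by several transcripts covered 147 transcripts. In a check added after the data were seen, 1013 of 10754 transcripts had at least 20% of their footprints in runs of codons with counts identical to another transcript, and which transcript such reads come from is uncertain.

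Footprints were summed over the whole coding sequence and over the codons beyond codon 50, and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, quasi-likelihood F test) in 1 fit of all 9 libraries for each readout, leaving 10607 and 10466 genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Levels are CPM (counts scaled to a common library size with TMM factors), and intervals are 95% intervals of the log2 fold change. Windows of 20 codons with enough footprints were tested for a shift within the gene with edgeR's diffSpliceDGE, with a Simes p per gene, over 105976 windows of 7158 genes. In 9299 genes with a mean of 50 or more footprints per library, the cumulative share of footprints was compared between groups at each codon. The footprints of a group's libraries were summed first, so deeper libraries weigh more. A gene was counted where the largest difference was 0.2 or more and the libraries of both groups did not overlap there. This count has no test. Of 18 gene lists, 17 had measured members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01 in all 3 comparisons, 51 tests adjusted together. DESeq2 1.42.0 was run as an alternative. Tables were handled with the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

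Genes are named by a fixed rule. It takes Pcsk9. For each comparison it takes, among genes past the threshold with a mean of 50 or more footprints per library and groups that do not overlap, up to 10 with the lowest and 5 with the highest log2 fold change beyond codon 50, and 5 and 5 over the whole coding sequence. It adds up to 10 genes by the gain of their leading window and the 5 largest cumulative differences towards the start. It also takes up to 4 members per list with the smallest p, and the 5 smallest adjusted p of each of the authors' tables. Any other gene was chosen after its values were seen, among them Pcbp2 in the windows and cumulative profiles and genes given for a comparison whose rule did not take them. This rule, the lists, the comparisons, the thresholds and all other settings not named below as added were set before the data were examined.

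The tests were tried on simulated data with the depths of these libraries. Counts were drawn independently for each library, so the resemblance of like-numbered libraries described below was left out. The cumulative share was simulated from a pooled vehicle profile, without further spread between libraries. Of 100 genes changed by a log2 of 1, 86% were recovered over whole coding sequences (10607 genes) and 85% beyond codon 50 (10466 genes), and of 100 changed by a log2 of 2, 100% in both, with 15 false among 201 calls and 12 among 197. For windows (6574 genes), 36% of 100 genes were recovered at a log2 of 2 and 96% at 3, with 4 false among 136 calls. A list of 20 genes shifted by 0.5 was recovered. With 40% of the footprints of 200 genes moved to codon 40, 99% were counted among 9299 genes, 69.5% of them with a codon within 1 of the true position.

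Whether the replicate numbers pair the libraries was checked by correlating deviations from the group means within numbers. The values were 0.27, 0.30 and 0.23 for 7f with vehicle and 0.61, 0.32 and 0.28 for 7l with 7f, each above the threshold of 0.1, so a fit with replicate number as a block is given beside those results, and 0.50, 0.40 and 0.02 for 7l with vehicle, which were not all above it. Alternatives were DESeq2, RLE normalisation, no low-count filter, fits of the 6 libraries of a comparison alone, other spans of codons, other window sizes and count minimums, other limits for the cumulative difference, an estimated correlation for the lists and leaving out each library in turn. Added after the data were seen were leaving out the 3 libraries numbered 1, leaving out AABR07000398.1, thinning each library to the smallest depth, counting from beyond codon 50 to 50 codons before the end, and an estimated correlation for the lists counted beyond codon 50. Pcsk9 was not among the coding sequences, and the settings meant for it were not run.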

Results

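Ribosome-protected fragments were counted in rat IEC6 cells, an established line from the small-intestinal epithelium. Cells had been given 4 µM of compound 7f (PF-06446846), 4 µM of compound 7l (PF-06649492) or vehicle for 60 min. Each of the 3 groups held 3 libraries, and each library was a map of footprint counts over 6003819 codons of 10762 coding sequences. The 7f libraries held 18621656, 8524265 and 8178369 footprints, the 7l libraries 19039078, 5024709 and 5321156, and the vehicle libraries 9133199, 14592083 and 3878718. The labels number the replicates without saying whether they were separate cultures. P-values of single genes, windows and library shares therefore measure only the spread between samples. The camera p-values of gene lists set list members against other genes, and rest on the spread across genes and the correlation set between them. Pcsk9, the gene named in the series title, was not among the coding sequences and was not analysed here. Col1a1 (median 11210 CPM, library-scaled footprint counts), Fn1 (10880 CPM) and Vim (5692 CPM) led the 18 extracellular matrix and fibroblast genes measured out of 22 listed. Of 20 intestinal epithelial markers, 3 were measured, Krt8 (median 556 CPM), Tjp1 (325 CPM) and Cdh1 (108 CPM), and 0 of 12 immune cell markers. The deposited code kept only transcripts that were the only expressed isoform of their gene, so a marker missing here was not necessarily silent.

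The share of all footprints lying in codons 1 to 50 was 15.6% ± 0.24 in 7f, 14.8% ± 0.62 in 7l and 13.7% ± 0.63 in vehicle (SD, n = 3). The two-sided exact permutation p was 0.1 for 7f against vehicle, 0.2 for 7l against vehicle and 0.2 for 7l against 7f, each 0.24 after Benjamini-Hochberg adjustment over 6 tests. The value 0.1 is the smallest value that 3 against 3 libraries allow. A single transcript, AABR07000398.1, took 7.06% ± 1.503 of the footprints in 7f, 5.99% ± 0.52 in 7l and 4.10% ± 1.37 in vehicle (SD, n = 3). Its exact permutation p was 0.2 for 7f and 0.1 for 7l against vehicle (adjusted 0.24 each) and 0.4 for 7l against 7f (adjusted 0.4). Of its footprints, 96.8% lay in 10 of its 380 codons, between codons 248 and 298.

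The comparison of 7f with vehicle asks which coding sequences gained or lost footprints in cells given the first compound. Footprints beyond codon 50 fell 11.8-fold on Car9, a membrane-bound carbonic anhydrase, from 246 ± 9.91 CPM in vehicle to 21.0 ± 4.60 CPM in 7f (SD, n = 3). They fell likewise on Bcap31, a membrane protein of the endoplasmic reticulum (113 ± 21.4 to 14.1 ± 0.41 CPM), and P3h3, a prolyl hydroxylase acting on collagen (38.8 ± 7.32 to 4.96 ± 0.15 CPM; SD, n = 3). The same held for Ptgis, the prostacyclin synthase (150.3 ± 24.1 to 24.0 ± 1.91 CPM), and Pcbp2, an RNA-binding protein (409 ± 26.0 to 72.2 ± 1.97 CPM; SD, n = 3 for each). Footprints rose 7.72-fold on Klf2, an immediate early transcription factor, from 13.4 ± 2.98 to 104.5 ± 24.5 CPM, and on Rhob, a small GTPase, from 191 ± 4.56 to 902 ± 192 CPM. Ddit3 (CHOP) and Atf3, transcription factors of the integrated stress response, rose from 2.81 ± 0.83 to 15.0 ± 2.13 CPM and from 4.37 ± 1.54 to 21.0 ± 10.1 CPM. The metal-binding metallothionein Mt2A rose from 4.23 ± 1.60 to 20.9 ± 7.49 CPM (SD, n = 3 for each). Mt2A has 62 codons, so only its last codons lie beyond codon 50.

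On the log2 scale, the changes beyond codon 50 in 7f were -3.56 for Car9 (SE 0.17, adjusted p = 3.4e-07), -3.00 for Bcap31 (SE 0.16, 9.9e-07), and -2.98 for P3h3 (SE 0.17, 1.7e-06) by edgeR's quasi-likelihood test. They were -2.65 for Ptgis (SE 0.17, 3.9e-06) and -2.50 for Pcbp2 (SE 0.12, 3.3e-07). Xdh, which encodes xanthine dehydrogenase, fell by 2.62 (adjusted p = 0.0022). Klf2 rose by 2.95 (SE 0.21, adjusted p = 1.2e-05), Ddit3 by 2.53 (5.7e-04), Atf3 by 2.29 (0.0067), Rhob by 2.24 (2.6e-05) and Mt2A by 2.18 (0.0061). The ribosomal protein gene Rpl27 fell by 3.43 (adjusted p = 3.0e-07, edgeR), from 529 ± 39 to 48.9 ± 6.59 CPM (SD, n = 3). RGD1563835 and RGD1560069, which fell by 3.44 and 3.74, hold counts identical to those of Rpl27 over runs of codons. These runs take 83.0% and 59.8% of their footprints and 51.5% of those on Rpl27, so the 3 values are not independent and the source of the shared footprints is uncertain. The unshared footprints were not tested alone. In the same way AABR07034131.1, which fell by 2.59, shares 71.4% of its footprints with Ptgis. Over whole coding sequences, which include codons 1 to 50, Car9 fell by 2.43, Ptgis by 2.44, P3h3 by 3.02 and Rpl27 by 1.47. Klf2 rose by 2.95, Mt2A by 2.45, Rhob by 2.11 and Ptp4a1, a protein tyrosine phosphatase that shares 94.5% of its footprints with LOC103693189, by 2.12.

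Immediate early genes, which cells induce within minutes of a stimulus, rose as a list in 7f (mean log2 fold change 0.98, adjusted p = 2.4e-37 by limma camera). With an estimated correlation between genes in place of the preset 0.01, the adjusted p = 0.023. Of 16 measured members, 7 rose, 0 fell and 9 did not pass the test over all genes, and 12 rose with p adjusted over the list alone. Jun rose by 1.78 to 191 ± 2.79 CPM from 55.2 ± 14.8 CPM (SD, n = 3), Klf6 by 1.67, Egr1 by 1.23 and Atf3 by 2.29 over the whole coding sequence. The integrated stress response list, targets of the transcription factor ATF4, rose too (mean 0.50, adjusted p = 3.0e-12 by camera; adjusted p = 0.039 with an estimated correlation). Of its 20 measured members, 5 rose over all genes tested and 7 adjusted over the list alone, among them Atf4 itself (0.95, from 116.5 ± 16.7 to 224 ± 22.4 CPM; SD, n = 3), Chac1, a glutathione-degrading enzyme (1.15), and Ddit3 (1.77). The p53 target list rose (mean 0.34, median 0.19, adjusted p = 2.0e-05 by camera, and adjusted p = 0.032 with an estimated correlation). Of its 12 members 7 lay above vehicle and 5 below, and 3 rose past the test over all genes. These were the growth-arrest gene Gadd45a (1.31), the kinase gene Plk2 (1.27) and the antiproliferative gene Btg2 (1.5). Beyond codon 50 the call of the list was lost with adjusted p = 0.068 with an estimated correlation, a setting chosen after seeing the data. Adjusted over the list alone, 5 rose and 1 fell, the cyclin gene Ccng1 (-0.52, adjusted p = 0.0095 over the list and 0.20 over all genes, edgeR), which passed over all genes without vehicle replicate 1 (-0.66). Atf3 stands in both the stress response and the immediate early list, and Btg2 in both the immediate early and the p53 list. Without vehicle replicate 2, Atf3 (1.98), Atf4 (0.88), Chac1 (1.03) and Btg2 (1.65) lost their whole-sequence calls, as did Atf4 (0.90), Chac1 (1.03), Ddit3 (1.69) and Btg2 (1.49) without 7f replicate 2 and Btg2 (1.48) without 7f replicate 3.

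**Figure D1:**
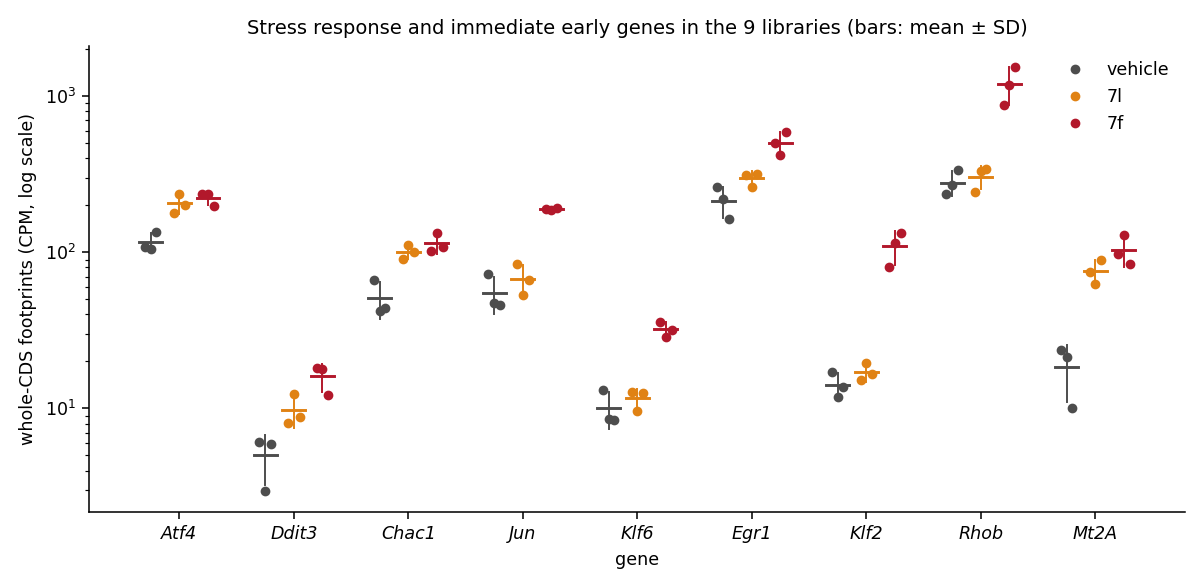
Whole-coding-sequence footprints of 9 genes in CPM (library-scaled counts) on a log axis, one point per library, in 7f, 7l and vehicle, with bars at each group mean and its SD. Jun lay at 191 ± 2.79 in 7f, 67.9 ± 15.4 in 7l and 55.2 ± 14.8 in vehicle, and Atf4 at 224 ± 22.4, 206 ± 28.6 and 116.5 ± 16.7 (SD, n = 3).

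Genes of protein translocation into the endoplasmic reticulum and of signal peptide handling had a mean log2 fold change of -0.10 in 7f, and the list did not pass (adjusted p = 0.060 by camera). Counted beyond codon 50 it passed (mean -0.15, adjusted p = 0.0088), a call lost with adjusted p = 0.70 with an estimated correlation, a setting chosen after seeing the data. Of 25 members, 1 fell, Dad1, a subunit of the oligosaccharyltransferase (-0.74, adjusted p = 0.024, edgeR), and 2 fell adjusted over the list alone. Cytosolic ribosomal proteins had a mean of -0.046 and a median of 0.025, which differ in sign, and did not pass as a list (adjusted p = 0.62 by camera). Beyond codon 50 they passed (mean -0.14, adjusted p = 0.0084), a call lost with adjusted p = 0.97 with an estimated correlation, the same later setting. Of 40 members, 1 fell (Rpl27, -1.47), and 2 adjusted over the list alone, where Rps8 (-0.52, adjusted p = 0.028 over the list and 0.12 over all genes, edgeR) joined it. Rps8 shares 70.5% of its footprints with LOC100363452, so their source is uncertain, as for Rpl27. Cholesterol synthesis genes, targets of SREBP2, had a mean of 0.064 (adjusted p = 0.68 by camera), with 0 of 21 members past the test over all genes or over the list alone.

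In total, 32 coding sequences gained and 77 lost footprints beyond codon 50 among 10466 tested (edgeR, Benjamini-Hochberg 0.05), and 29 gained and 64 lost them over the whole sequence among 10607. In all 109 and all 93 the 3 libraries of one group lay above the 3 of the other. Chance gives this in 10% of unselected genes, and these genes were selected by a test on the same libraries. With replicate number as a block the counts were 229 (91 gained, 138 lost) and 195 (79 and 116), and without vehicle replicate 1 they were 162 (62 and 100) and 134 (57 and 77). With the 3 libraries numbered 1 left out, a setting chosen after seeing the data, they were 255 (112 and 143) and 255 (128 and 127), so the excess of losses over whole sequences was not kept. The beyond-50 total was 71 without 7f replicate 2, 72 without 7f replicate 3 and 70 without vehicle replicate 2, where Atf3 (2.02) lost its call. The whole-sequence total was 51, 55 and 50 without these and 60 without vehicle replicate 3.

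The placement of footprints within coding sequences was compared without a test. The share of footprints lying in the first codons of a sequence, summed from codon 1 on, was taken with each group's libraries pooled. In 7f it exceeded that in vehicle by 0.2 or more in 119 of 9299 genes, with the 3 libraries of each group apart. The reverse held in 10. The codon of the largest gap had a median of 76 over the 119 genes (interquartile range 44 to 134.5), at or before codon 100 in 73. By codon 41 of Car9, the 7f libraries held 51.5, 61.2 and 62% of its footprints, the 7l libraries 29.9, 42.3 and 42.6% and the vehicle libraries 9.32, 8.84 and 7.78%. The largest gaps were 0.590 on Rpl27 and 0.534 on RGD1563835, both at codon 28, on transcripts that share footprints. Next were 0.516 at codon 63 of the histone gene Hist2h2be, 0.486 at codon 41 of Car9 and 0.459 at codon 114 of Pcyox1l, a prenylcysteine oxidase-like gene. The early and late counts of 119 and 10 were 250 and 40 without 7f replicate 1, 212 and 43 without vehicle replicate 1 and 215 and 64 without vehicle replicate 2. The late count was 20 without 7f replicate 2 and 19 without vehicle replicate 3.

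**Figure D2:**
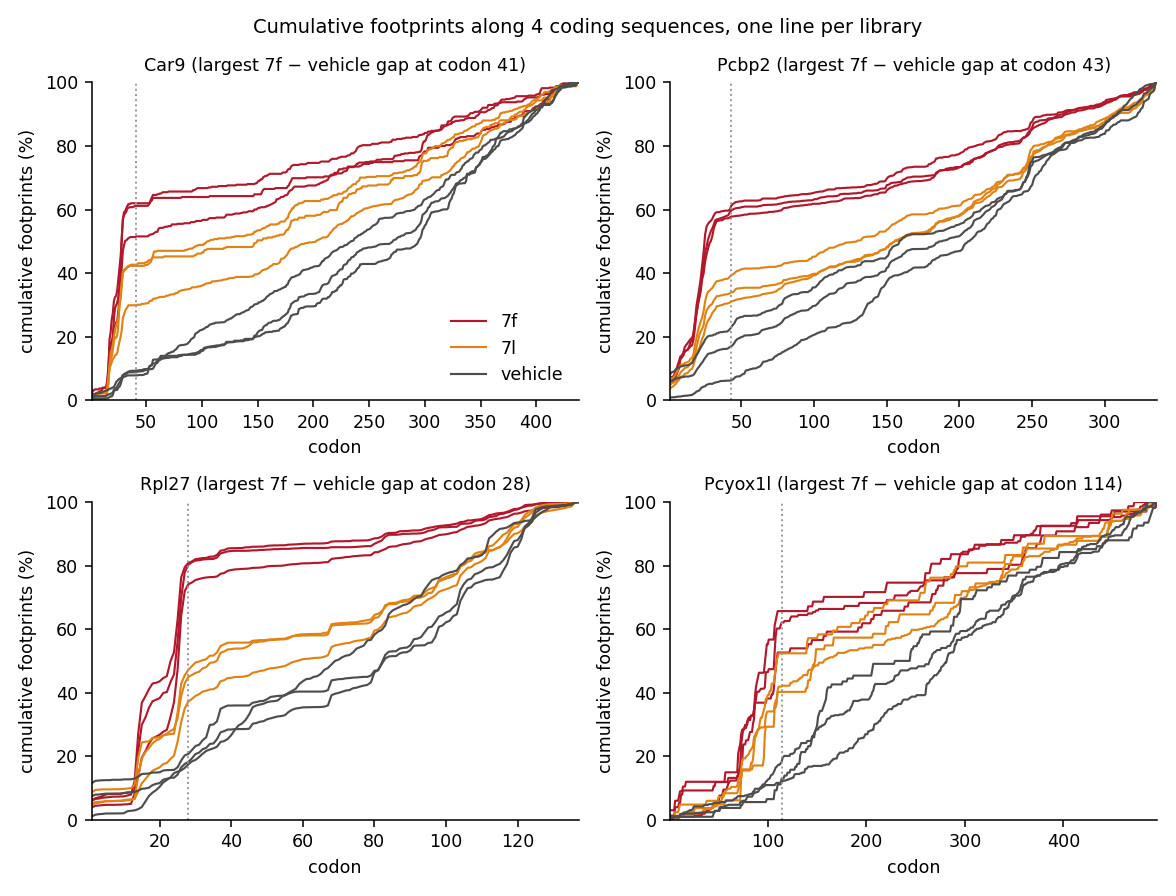
Cumulative share of footprints in percent against codon number along Car9, Pcbp2, Rpl27 and Pcyox1l (Pcbp2 was chosen for this plot after its values were seen), one line per library for 7f, 7l and vehicle, with a dotted line at the largest gap between 7f and vehicle. At codon 43 of Pcbp2 the 7f libraries had passed 57.8, 59.7 and 61.2%, the 7l libraries 31, 39.3 and 34% and the vehicle libraries 6.28, 16.9 and 23.0%.

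In windows of 20 codons, footprints shifted within 20 of 7158 genes in 7f (edgeR diffSpliceDGE, Simes p per gene, Benjamini-Hochberg 0.05). The window with the largest gain relative to its gene lay within the first 100 codons in 15 of the 20. That window passed the test itself in 15 of the 20, of which 12 had it within the first 100 codons. Over all genes 23 windows passed with a gain and 21 with a loss. All gains and losses of windows given here are relative to the change of the gene itself. Car9 and Ptgis fell over their whole sequences, so a gain in their windows need not be a rise in footprints. Changes of the windows without regard to their gene were not tested. Codons 1 to 20 gained on Car9 (log2 3.06 relative to the gene, adjusted p of the window 2.4e-06), on RGD1563835 (3.89, 3.2e-08) and on Ptgis (2.34, 0.0030). The adjusted Simes p of these genes was 3.6e-06, 1.5e-08 and 0.0062. Codons 21 to 40 gained on Exoc4, an exocyst subunit (2.64), and on Igf2r, the receptor for insulin-like growth factor 2 and mannose 6-phosphate (2.53). Codons 41 to 60 gained on Tm9sf3 (3.50), the adaptor gene Crk (2.93) and Ltbp1, which binds latent TGF-beta (2.37). Later windows led in Macf1, a cytoskeletal linker (codons 4641 to 4660, 2.81), and Brd4, a bromodomain protein (codons 581 to 600, 2.80). The count was 91 with replicate number as a block, 291 without the 3 libraries numbered 1 (chosen after seeing the data), and 190 without vehicle replicate 1. It was 11 without 7f replicate 2, and 12 without 7f replicate 3 or vehicle replicate 2. Single libraries ended the calls of Brd4 (2.98), Crk (2.58) and Macf1 (2.75) when vehicle replicate 2 was left out, and of Tm9sf3 without 7f replicate 2 (3.28). Lost too were that of Igf2r without 7f replicate 2 (2.34), vehicle replicate 2 (2.21) or vehicle replicate 3 (2.26), of Ltbp1 without 7f replicate 3 (2.14) or vehicle replicate 2 (2.22), and of Ptgis without any 7f library or vehicle replicate 2 (2.26 to 2.50). In windows of 40 codons Tm9sf3 was not called (0.46).

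The comparison of 7l with vehicle asks the same of the second compound at the same dose and time. Footprints beyond codon 50 fell on P3h3 from 38.8 ± 7.32 to 5.75 ± 0.16 CPM, and on Car9 from 246 ± 9.91 to 49.8 ± 5.35 CPM (SD, n = 3). On Bcap31 they fell from 113 ± 21.4 to 25.4 ± 2.71 CPM and on Ptgis from 150.3 ± 24.1 to 43.7 ± 7.81 CPM (SD, n = 3 for each). They rose on the metallothionein gene Mt1 from 12.4 ± 1.78 to 50.2 ± 13 CPM and on Mt2A from 4.23 ± 1.60 to 18.3 ± 6.99 CPM (SD, n = 3). They also rose on Ddit3 from 2.81 ± 0.83 to 8.44 ± 2.60 CPM and on Ptp4a1 from 9.01 ± 1.39 to 21.5 ± 2.12 CPM (SD, n = 3 for each). The log2 changes were -2.77 for P3h3 (SE 0.17, adjusted p = 2.9e-05, edgeR), -2.31 for Car9 (SE 0.16, 4.6e-05), -2.16 for Bcap31 (SE 0.16, 4.6e-05) and -1.78 for Ptgis (SE 0.16, 3.8e-04). Smaller falls were those of Parl, a mitochondrial rhomboid protease (-1.15), Ctif, a factor of cap-binding-complex-dependent translation (-1.14), Pttg1ip (-1.12), Pcyox1l (-1.03) and Pcbp2 (-0.82, adjusted p = 0.0099). AABR07034131.1 (-2.27) and LOC103693189 (1.30) were called with the partners whose footprints they share, Ptgis and Ptp4a1. Mt1 rose by 2.00 (adjusted p = 0.0099), Mt2A by 1.98 (0.044), Ddit3 by 1.65 (0.047) and Ptp4a1 by 1.30 (0.0099, edgeR), and over whole coding sequences the creatine transporter gene Slc6a8 rose by 1.23. Mt1 and Mt2A have 62 codons each, so only their last codons lie beyond codon 50. Over its whole sequence Mt1 rose by 1.55, a call lost without any 7l library, vehicle replicate 2 or vehicle replicate 3 (1.33 to 1.69).

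The integrated stress response list rose in 7l (mean 0.30, median 0.15, adjusted p = 5.0e-09 by camera). The call was lost with adjusted p = 0.074 with an estimated correlation. Of 20 members, 19 lay above vehicle, 0 passed over all genes and 3 passed adjusted over the list alone. Whole-sequence values were 0.82 for Atf4 (adjusted p = 0.068, edgeR), 0.97 for Chac1 (0.079) and 1.00 for Ddit3 (0.81). Atf4 (0.82) and Chac1 (0.97) passed over all genes with DESeq2 and with replicate number as a block, and Chac1 (1.22) also without vehicle replicate 1. Both passed with the libraries numbered 1 left out (0.87 and 1.29), a setting chosen after seeing the data. Immediate early genes had a mean of 0.11 in 7l (adjusted p = 0.17 by camera; 0 of 16 past the test over all genes or the list alone), with Jun at 0.30 and Egr1 at 0.47. The p53 targets had a mean of 0.037 (adjusted p = 0.68 by camera), with 0 of 12 past the test over all genes and, adjusted over the list alone, Gadd45a up (0.95, adjusted p = 0.057 over all genes, edgeR) and Ccng1 down (-0.59, 0.38).

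In total, 12 coding sequences gained and 15 lost footprints beyond codon 50 in 7l (edgeR, Benjamini-Hochberg 0.05), and 7 gained and 11 lost them over the whole sequence. All 27 beyond-50 calls were also calls in 7f, 12 higher and 15 lower in both and 0 opposite, against 0.037 and 0.110 for independent lists. In 20 simulations of unchanged groups sharing the vehicle libraries, which made 0.35 calls on average, the overlap was at most 0. The simulations leave out the effects and the independent lists leave out the shared vehicle libraries, which could not be split, so the excess over either is no measure of a shared effect. The beyond-50 total was 7 without 7l replicate 1, 13 without 7l replicate 2, 7 without 7l replicate 3 and 4 without vehicle replicate 2. The whole-sequence total was 7, 9, 11 and 3 without the same libraries. P3h3, Car9, Bcap31 and Ptgis kept their beyond-50 calls without each library, whereas those of Mt1 (1.91) and Ptp4a1 (1.16) were lost without vehicle replicate 2. So were that of Ptp4a1 (1.21) without 7l replicate 1, and those of Ddit3 (1.37 to 1.83) and Mt2A (1.67 to 2.15) without any 1 of the 6 libraries. Also lost were the calls of Parl (-1.23 to -1.05) and Pcbp2 (-0.84 to -0.79) without any 7l library or vehicle replicate 2. Pttg1ip (-1.19 to -1.0) lost its call without these or vehicle replicate 3, and Pcyox1l (-1.11 to -0.83) without any but vehicle replicate 3. The calls ended of Ctif (-1.15 to -1.05) and AABR07034131.1 (-2.45 to -2.30) without 7l replicate 1, 7l replicate 3 or vehicle replicate 2, and of LOC103693189 without 7l replicate 1 (1.22) or vehicle replicate 2 (1.15). The whole-sequence call of Slc6a8 (1.08 to 1.19) ended without 7l replicate 2, 7l replicate 3, vehicle replicate 2 or vehicle replicate 3. With the 6 libraries of this comparison alone, Pcbp2 (-0.82), Pttg1ip (-1.12), Pcyox1l (-1.03), Mt2A (1.99), Ddit3 (1.64) and, over whole sequences, Slc6a8 (1.23) were not called. Counted from beyond codon 100, Ctif (-1.06), Pttg1ip (-1.11) and Ddit3 (1.75) lost their calls, and from beyond codon 30 Pcyox1l (-1.02) and Ddit3 (1.45).

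Footprints lay nearer the start in 7l than in vehicle in 53 of 9299 genes and nearer the end in 5. Of the 10 splits of the 6 libraries, the real one included, 3 gave a count as large as 53 (highest 122). The median codon of the largest gap was 108 (interquartile range 64 to 181), at or before codon 100 in 26 of the 53. The largest gaps were on Dnph1, a nucleotide hydrolase (0.397, codon 44), Hist2h2be (0.359, codon 73), Tmem219 (0.327, codon 49), the anion transporter gene Slc26a11 (0.319, codon 213) and Pcbp3 (0.305, codon 33). In windows, footprints shifted within 2 genes (edgeR diffSpliceDGE), Car9 and RGD1563835, both towards codons 1 to 20 (log2 2.50 and 2.38). The adjusted Simes p was 0.0041 for each gene, and the adjusted p of the windows 0.0034 and 0.0087. The early and late counts, which have no test, were 211 and 71 without 7l replicate 1, 95 and 27 without vehicle replicate 1 and 142 and 41 without vehicle replicate 2. The late count was 9 without 7l replicate 2 or 7l replicate 3 and 14 without vehicle replicate 3. The window count was 0 without 7l replicate 2 or 7l replicate 3, 9 without vehicle replicate 1, 1 without vehicle replicate 2 and 5 without vehicle replicate 3. The call of Car9 was lost without any of these but vehicle replicate 1 (2.30 to 2.49), and that of RGD1563835 without 7l replicate 2 (2.26), 7l replicate 3 (2.21) or vehicle replicate 2 (2.16), and in windows of 40 codons (0.91).

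The comparison of 7l with 7f asks where the compounds differed at the same dose and time. Klf2 lay at 15.7 ± 1.05 CPM beyond codon 50 in 7l against 104.5 ± 24.5 CPM in 7f (SD, n = 3), a log2 difference of -2.74 (95% interval -3.19 to -2.29, adjusted p = 5.0e-05, edgeR). Rhob was lower in 7l by -2.11 (-2.48 to -1.74), Jun by -1.51 (-1.98 to -1.04), Klf6 by -1.41 (-1.88 to -0.94) and Plk2 by -1.09 (-1.45 to -0.74). Footprints that 7f had lowered lay higher in 7l on Rpl27 (2.66, 2.33 to 2.99, adjusted p = 3.9e-06), Pcbp2 (1.68, 1.43 to 1.93, 2.3e-05) and Car9 (1.26, 0.90 to 1.62, 0.010, edgeR). RGD1563835 (2.71) and RGD1560069 (3.29), which share footprints with Rpl27, were called with it. Against vehicle, Rpl27 in 7l had a log2 change of -0.77 (adjusted p = 0.053, edgeR), Klf2 of 0.21, Rhob of 0.13 and Jun of 0.25 beyond codon 50, none of which passed the test.

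**Figure D3:**
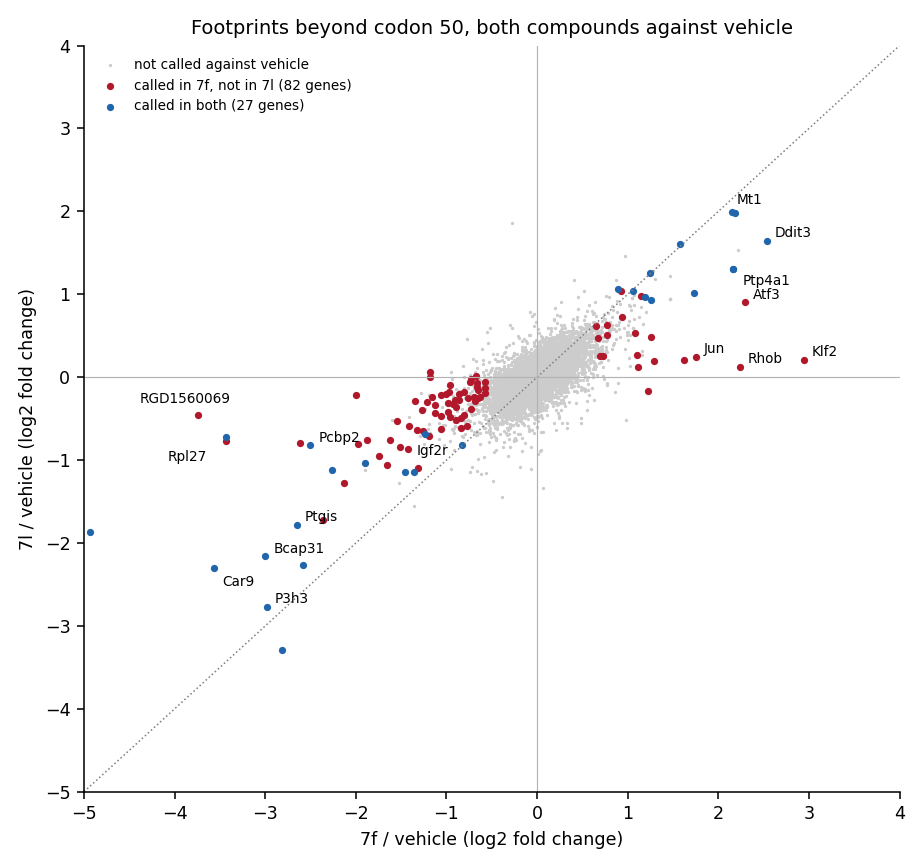
Log2 fold change of footprints beyond codon 50 against vehicle for 7f (horizontal) and 7l (vertical), one point per coding sequence, coloured by the comparisons in which it was called, with a dotted line where both changes are equal. Of the 109 genes called in 7f, 27 were also called in 7l, and Klf2 (2.95 and 0.21) and Rpl27 (-3.43 and -0.77) lie far from the line of equal change.

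Several of the genes named above did not pass the test of the difference between the compounds. Its 95% interval on the log2 scale was -0.20 to 0.64 for P3h3, 0.48 to 1.19 for Bcap31 (adjusted p = 0.083, edgeR), 0.51 to 1.22 for Ptgis (0.079) and 0.32 to 0.80 for Igf2r (0.084). For the genes that rose with 7f, it was -1.42 to -0.36 for Ddit3 (adjusted p = 0.50), -2.12 to -0.66 for Atf3 (0.26), -0.55 to 0.09 for Atf4, -0.68 to 0.37 for Mt1, -0.86 to 0.45 for Mt2A and -1.21 to -0.51 for Ptp4a1 (0.070, edgeR). Of the 82 genes called beyond codon 50 in 7f and not in 7l, 13 differed between the compounds by this test.

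Immediate early genes were lower as a list in 7l than in 7f (mean -0.88, adjusted p = 3.7e-58 by camera; adjusted p = 0.023 with an estimated correlation). Of 16 members 16 lay lower, 3 past the test over all genes (Jun -1.48, Klf6 -1.45 and Btg2 -1.62 over whole coding sequences) and 14 adjusted over the list alone. The p53 targets were lower (mean -0.30, adjusted p = 8.9e-08 by camera; adjusted p = 0.023 with an estimated correlation), with Plk2 (-1.10) and Btg2 past the test over all genes and over the list alone. The whole-sequence calls of Jun (-1.48 to -1.34) and Klf6 (-1.48 to -1.35) were lost without 7f replicate 1, 7f replicate 3, 7l replicate 2 or 7l replicate 3, that of Plk2 (-1.18 to -0.98) without any of the 6 libraries but 7f replicate 2, and that of Btg2 (-1.76 to -1.58) without any. The integrated stress response list was lower (mean -0.20, median -0.044, adjusted p = 0.0013 by camera), a call lost with adjusted p = 0.43 with an estimated correlation. By edgeR 0 members passed over all genes and 2 adjusted over the list alone. With replicate number as a block Atf3 (-1.57), a member of this list and the immediate early one, passed over all genes, as did Dusp1 (-0.92) of the immediate early list and Dad1 (0.67) of the translocation list, and all 3 passed with DESeq2, as did Ppp1r15a (-0.80) of the stress response list. Translocation and signal peptide genes were higher (mean 0.087, adjusted p = 0.046 by camera), a call lost with adjusted p = 0.94 with an estimated correlation. It was also lost without any library but 7l replicate 1 and vehicle replicate 1 (means 0.033 to 0.10), and 0 of 25 members passed over all genes, 1 (Dad1, 0.68) over the list alone.

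In total, 12 coding sequences were higher and 5 lower in 7l than in 7f beyond codon 50 (edgeR, Benjamini-Hochberg 0.05), and 6 higher and 6 lower over the whole sequence. Emc7, a subunit of the membrane protein insertion complex of the endoplasmic reticulum, was higher by 0.83 over the whole sequence (adjusted p = 0.048), a call lost with RLE normalisation (0.83). With replicate number as a block the totals were 48 (35 higher, 13 lower) and 35 (24 and 11). With DESeq2 they were 51 (36 and 15) and 37 (23 and 14), so the even balance over whole sequences was not kept. The beyond-50 total of 17 was 9 without 7f replicate 1, 10 without 7f replicate 2, 6 without 7f replicate 3, 11 without 7l replicate 1, 8 without 7l replicate 2 and 6 without 7l replicate 3. The whole-sequence total of 12 was 6 without 7f replicate 1, 7f replicate 3, 7l replicate 2 or 7l replicate 3. Klf2, Rhob, Rpl27 and Pcbp2 kept their beyond-50 calls without each library. Car9 lost its call without 7f replicate 3 (1.27) or 7l replicate 3 (1.16), Jun (-1.52 to -1.35) without any of the 6 but 7l replicate 1, Plk2 (-1.18 to -0.97) without any but 7f replicate 2. Klf6 (-1.55 to -1.28), and Emc7 (0.76 to 0.89) and Btg2 (-1.76 to -1.58) over whole sequences, lost theirs without any 1 of the 6.

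Footprints lay nearer the start in 7l than in 7f in 7 genes and nearer the end in 22. Of the 10 splits of the 6 libraries, the real one included, 7 gave a count as large as 7 (highest 48). Each other split took the larger of its early and late counts, and the real split its early count alone, so these counts are not alike. The late count of the real split, 22, also lay under the highest other count of 48. The largest gaps towards the start were on LOC108348111 (0.252, sharing 94.5% of its footprints with Sdhaf1), AABR07028748.1 (0.230), the kinetochore gene Ndc80 (0.217), Mbtps2, the site-2 protease (0.215), and Fam117a (0.204). The rule names only gaps towards the start, so the 22 genes of the other direction are not named for their gaps. With the first 10 and last 5 codons left out, the gap of AABR07028748.1 was 0.0407, under the limit of 0.2. The median codon of the 7 gaps was 192. The early and late counts were 100 and 131 without 7l replicate 1, 36 and 59 without 7f replicate 1 and 16 and 35 without 7f replicate 2. In windows, footprints shifted within 0 of 7158 genes by edgeR diffSpliceDGE, 40 at an unadjusted p under 0.05, and within 1 with replicate number as a block. The 40 are fewer than that limit gives by chance. The test was thus strict here, and the 0 does not show equal placement in both compounds.

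The authors' own tables compare footprints downstream of their stall position or, for genes without one, over an inner part of the coding sequence. At an adjusted p under 0.05 they hold 95 genes for 7f (69 lower, 26 higher) and 18 for 7l (13 lower, 5 higher), of which 68 and 13 were among the 109 and 27 genes called above. Their smallest adjusted p for 7f stand at Car9 (log2 -3.61, 4.81e-48), RGD1563835 (-3.37), Pcbp2 (-2.52), Fam13b (-5.26) and Naga (-2.71), a lysosomal glycosidase, and for 7l at Car9 (-2.33, 1.76e-18), P3h3 (-2.84), Ptgis (-1.76), Msln (-1.31) and the transcript without a symbol ENSRNOT00000089409 (1.11), values of their DESeq fit. Msln, the mesothelin gene, had a log2 change of -0.049 beyond codon 50 in 7l (edgeR), where the authors counted downstream of their stall position at codon 451.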

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

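The settings that leave out the 3 libraries numbered 1, thin each library to the smallest depth, leave out AABR07000398.1, end 50 codons before the last or test the lists beyond codon 50 with an estimated correlation were chosen after seeing the data, and all others were planned. Of the counts, 38 stayed within 1.5 times their value when a single library was left out and 43 moved further, 54 stayed and 27 moved under the other planned settings, and 18 stayed and 10 moved under the added ones. Of the values of named genes and lists, 664 kept their direction and side of the threshold without a single library, 144 kept their direction and lost the call and 2 gained one. Under the other planned settings 721 kept both, 19 lost and 11 gained a call, and under the added ones 333, 22 and 5. With the first 10 and last 5 codons left out, the largest cumulative difference moved to 0.637 for Rpl27 in 7f and to 0.0407 for AABR07028748.1 in 7l against 7f. No named gene or list changed direction under the settings run for them, which leave out the count table read by its column descriptions. The settings meant for Pcsk9 were not run, as no transcript of it was among the coding sequences. With each library thinned to the smallest depth, 88 genes were called beyond codon 50 for 7f and 19 for 7l against vehicle. Simulations recovered 86% of whole-sequence changes with a log2 of 1 and 36% of window shifts with a log2 of 2. They did not vary the depth and left out the resemblance of like-numbered libraries.

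With the count table read by its column descriptions, which exchange 7f and vehicle, the 93 genes of 7f against vehicle turned direction (64 higher, 29 lower), by the exchange itself. DESeq2 gave 144 genes for 7f against vehicle, 30 for 7l against vehicle and 37 for 7l against 7f over whole coding sequences, and 51 for 7l against 7f beyond codon 50. With replicate number as a block the whole-sequence counts were 195, 43 and 35, those beyond codon 50 229, 49 and 48, and the window counts 91, 12 and 1. With the 3 libraries numbered 1 left out, 7f against vehicle gave 255 genes over whole sequences and 255 beyond codon 50, the windows 291, 10 and 5 genes, and the cumulative differences 329 early and 71 late, 239 and 74, and 133 and 169. With the 6 libraries of a comparison alone, 7l against vehicle gave 10 genes over whole sequences and 14 beyond codon 50, and 7l against 7f 1 gene in windows. Thinned libraries gave 10 genes for 7l against vehicle over whole sequences, and counting from beyond codon 100 gave 17. A limit of 0.1 for the cumulative difference counted 1059 early and 252 late genes, 586 and 174, and 258 and 382, by its construction. A minimum mean of 20 footprints gave 185 and 41, 111 and 27, and 35 and 64, and one of 200 footprints 53 and 2, 14 and 0, and 1 and 9, from more and from fewer genes. With an estimated correlation 5 of the 8 list calls held, and beyond codon 50 with an estimated correlation 4 lists were called. Apart from settings that alter the libraries or genes counted, the cause was not tested.

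Leaving out 1 library at a time gave 50 to 134 genes for 7f against vehicle, 3 to 20 for 7l against vehicle and 6 to 10 for 7l against 7f over whole sequences, and 70 to 162, 4 to 26 and 6 to 11 beyond codon 50. In windows it gave 11 to 190 genes for 7f and 0 to 9 for 7l against vehicle by edgeR, where 91 passed an unadjusted p of 0.05 with all libraries. The early cumulative differences ranged from 138 to 250, 63 to 211 and 9 to 100, and the late ones from 14 to 64, 9 to 71 and 25 to 131. Among the settings chosen after seeing the data, thinning ended the calls of Slc6a8 (1.22), Ctif (-1.08), Pcyox1l (-1.01), Mt2A (2.06) and Ddit3 (1.53) in 7l against vehicle and of Btg2 (-1.44), Emc7 (0.79) and Klf6 (-1.35) in 7l against 7f. Leaving out the libraries numbered 1 ended those of Ctif (-1.04), Btg2 (-1.79) and Plk2 (-0.84, and -0.85 over the whole sequence). Ending 50 codons before the last ended those of AABR07034131.1 (-1.90), Pttg1ip (-0.97), Pcyox1l (-0.98), Ddit3 (1.62), Jun (-1.49) and Klf6 (-1.46). With the first 10 and last 5 codons left out or with the 6 libraries alone, Mt1 (1.21 and 1.55) was not called over the whole sequence in 7l against vehicle.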

Other observations

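Further gene groups, tested with camera over whole coding sequences, are given with their values. Mean log2 fold changes of cholesterol synthesis genes (21 measured) were 0.064 in 7f and 0.019 in 7l against vehicle and -0.045 in 7l against 7f (adjusted p = 0.68, 1.00 and 0.64). The unfolded protein response and its chaperones (18 genes) had -0.039, -0.045 and -0.0053 (adjusted p = 0.68, 0.68 and 1.00), and cytosolic heat shock proteins (12 genes) -0.040, -0.13 and -0.086 (adjusted p = 0.68, 0.099 and 0.59), with Hspd1, a mitochondrial chaperone, past the test in 7f adjusted over the list alone. Ribosomal proteins (40 genes) had 0.0027 in 7l against vehicle (adjusted p = 1.00, where the test pointed down) and 0.049 in 7l against 7f (0.28), where 1 member, Rpl27, was higher. Counted beyond codon 50, that list passed in 7l against 7f (mean 0.11, adjusted p = 0.0044), a call lost with adjusted p = 0.93 with an estimated correlation, a setting chosen after seeing the data. The translocation list had -0.016 in 7l against vehicle (adjusted p = 0.68). NF-kappaB targets (6 genes) had 0.14, 0.23 and 0.087 (adjusted p = 0.68, 0.21 and 0.68), and Irf1 (0.87) and Ptgs2 (1.19), a prostaglandin synthase, passed in 7l adjusted over the list alone.

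In the order 7f against vehicle, 7l against vehicle and 7l against 7f, the other lists had these means, by camera. Translation factors (18 genes) had -0.014, -0.0017 and 0.013 (adjusted p = 1.00, 1.00 and 0.98), and ribosome rescue and quality control (20 genes) -0.028, 0.017 and 0.045 (0.90, 0.90 and 0.68). Proliferation genes (19) had -0.066, -0.021 and 0.045 (0.64, 0.72 and 0.68), oxidative phosphorylation (19) -0.0079, 0.023 and 0.031 (1.00, 0.87 and 0.68) and the proteasome (20) -0.044, 0.0057 and 0.050 (0.68, 1.00 and 0.60). Cytoskeleton and SRF targets (19) had 0.014, -0.0077 and -0.021 (0.90, 1.00 and 0.79), extracellular matrix and fibroblast genes (18) -0.073, -0.056 and 0.017 (0.68, 0.68 and 1.00), and the 3 intestinal markers -0.018, 0.0071 and 0.025 (1.00 each). Mean, median and direction of the test differed in sign in 7l against vehicle for cholesterol synthesis, ribosomal proteins, translation factors, ribosome rescue, oxidative phosphorylation, cytoskeleton, intestinal and NF-kappaB genes, and in 7l against 7f for the unfolded protein response and the extracellular matrix. Beyond codon 50 the fold changes of both compounds against vehicle correlated across genes with r = 0.698. In simulations where only the vehicle libraries were shared, r was 0.504. The covariance was 0.0501 against 0.0322 in the simulations, and genes are not independent replicates. The simulations leave out the resemblance of like-numbered 7f and 7l libraries, so the excess is no measure of a shared effect.

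Of the tests that follow, those chosen after the result was seen are the effect of depth on the numbers of genes called in 7f and 7l, the splits for the cumulative differences and the repeated thinning draws, which were added once a single draw had been seen. Early placement of footprints in 7f, counted in 119 genes, was weighed against a library-wide shift towards the start, depth and the other splits of the libraries. After each library was reweighted by codon number to the same share along coding sequences, 79 genes were counted early and 28 late, against 119 and 10 before. More genes thus stayed early than late with a shift by codon number evened out, and the early count met the bound set for that test. No other split was reweighted, and the highest of them gave 91 without reweighting. A shift by relative position was not evened out either, so a library-wide shift stays open as a cause. With all libraries thinned to the smallest depth, 251.5 genes were early and 72 late (medians of 10 draws), against 119 and 10 at full depth, and as the interval of their ratio of 3.529 (over the draws 3.12 to 4.26; counting interval 2.72 to 4.59) includes the bound of 3 set for that test, an effect of depth stays open. Genes were still chosen by their mean at full depth, so they held fewer footprints at the same limit of 0.2. Sampling noise can then add genes in both directions, and the counting interval takes genes as independent, so the ratio cannot settle the effect of depth. The median codon of the early genes was 76. The lowest among the other 9 splits was 84.5, taken over their early and late genes together, so these medians are not alike. A position nearer the start than in other splits stays open as well. An effect of 7f itself on these sequences stays open too and was not tested.

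More genes were called in 7f (109) than in 7l (27) beyond codon 50. With each library thinned to the smallest depth the counts were 88 and 19, a ratio of 4.632, which argues against depth as the cause. The spread between libraries, as the median SD of log2 CPM in 7l over that in 7f, was 1.011, and whether a larger spread in 7l could lower its count stays open. A difference between the compounds is the biological explanation that the groups give, and 17 genes differed between them by a direct test.

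Immediate early genes were higher in 7f than in vehicle. The median difference of the list within replicate numbers was 0.57 at its smallest (0.5687), then 0.94 and 1.30, which argues against a single pair handled differently. The list's median of 0.88 lay at percentile 100 of 10000 random lists matched for coding length and footprint level (highest 0.21), which argues against length or level as the cause. In 7l, the other treated group, the list had a mean of 0.11 against vehicle (adjusted p = 0.17 by camera) and of -0.88 against 7f (16 of 16 members lower), values looked at after the result, which argue against handling shared by both treated groups. Handling of the 7f libraries alone was not tested.

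With 3 libraries against 3, the 10 splits are too few for a share under 0.05. Over whole coding sequences 1, 2 and 1 of the 10 splits gave as many genes as the real one for 7f against vehicle (93, highest other 0), 7l against vehicle (18, highest other 93) and 7l against 7f (12, highest other 0), and beyond codon 50 likewise 1, 2 and 1 (109 and 0, 27 and 88, 17 and 0). In windows 5, 5 and 10 of the splits gave as many (20 and 471, 2 and 1156, 0 and 68, by edgeR, the last with 40 genes at an unadjusted p under 0.05 and 1 with replicate number as a block). For the cumulative differences 1, 3 and 7 did (119 and 91, 53 and 122, 7 and 48), and for the lists 8, 7 and 5 (3 and 7, 1 and 8, 4 and 5). For the cumulative differences each other split took the larger of its early and late counts. In 7l against 7f the real split was given its early count of 7, though its late count was 22, so that comparison is not like for like. The splits with the most windows joined vehicle replicate 1 with 7f replicate 1 or with 7l replicate 1. The split of 7l replicates 1 and 3 with vehicle replicate 1 from the rest gave the 93 and 88 genes. Splits that joined libraries numbered 2 or 3 but parted those numbered 1 gave 0 genes and 0 windows. For the windows this points to a resemblance of the libraries numbered 1. The gene counts do not single them out, as the other splits that joined libraries numbered 1 gave 0 genes. Among the splits that part every pair of like-numbered libraries, as the real one does, the highest other count for 7f against vehicle was 0 genes, 0 windows, 43 cumulative differences and 4 lists, for 7l against vehicle 0 genes, 0 windows, 24 and 2, and for 7l against 7f 0, 0, 6 and 1. The others join like-numbered libraries on a side.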
